A study of Mus musculus with 3 samples.

How the data were processed

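RNA from 3 C2C12 lines, 1 array each and no replicates, was measured on Affymetrix mouse arrays. The deposited signal table gives an intensity (GCOS signal) per probe set, scaled by the authors so that the 2% trimmed mean is 1000 on each array. The deposited ratio table gives, per the file headers, the log2 ratio of each line to control RNAi, rounded to 0.1, with a change call. GCOS is named in the submitters' processing notes, and its version and settings are not given in the sources used here. A separate control sample is not used here.

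The ratio table has 1 column of identifiers, and the change calls of all 3 lines run in sorted blocks. The ratio of the array labelled FoxO1 followed that array's own signal minus the other arrays with r of 0.58 across probe sets, while those of the arrays labelled FoxO3 and FoxO4 gave -0.01 and -0.00. Only the FoxO1 ratio was therefore read per probe set, and the other ratio columns were used as column totals. The control signal was derived as the log2 signal of the array labelled FoxO1 minus its deposited ratio. Its 2% trimmed mean was 1043, beside 1000 on the 3 arrays. This implied control is not a measured array. Whether it equals the signal of the control array was not tested, so every value given for it is approximate. The main comparisons were the array labelled FoxO1 against the control and each other array against the mean of the remaining 2. Comparing the arrays labelled FoxO3 and FoxO4 with the implied control was added after the values were seen. The counts common to all 3 arrays and the correlations depend on that addition.

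Signals were floored at the 20th percentile of their array before log2, and the deposited FoxO1 ratio was used without a floor. A gene's value was the median over probe sets with its symbol alone. Of the probe sets, 34958 had 1 symbol, 932 several and 9211 none. Of the first, 34754 were matched by Entrez identifier to the RefSeq gene table of assembly GRCm38.p6. That table was used for names and for the place of genes on chromosomes. The threshold was 2-fold, a log2 value of 1. The median over 33 gene lists was given with its percentile among 10000 random lists matched on 10 bins of signal. List members were matched by current symbol, and by an older name only where no other gene now bears it. This matching was corrected after list values were seen, because older names had drawn in Pigq for Gpi1 and Nckap1 for H19.

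The lists, thresholds, comparisons and the rule for naming genes were written before the data were examined. The rule named the FoxO genes; the 12 highest and 12 lowest genes of each array's main comparison; 6 and 6 of each pair; 8 and 8 of the genes common to all 3 arrays or particular to 1; and up to 2 highest and 2 lowest members per list, plus members behind a list's count. Such genes needed a symbol that is not a clone name, probe sets of 1 sign and a signal above the array's median. A gene with 1 probe set meets the sign rule by construction. Such genes made up 10 of the 12 highest and 11 of the 12 lowest for FoxO1 against control. They were 8 and 9 for FoxO3 against the others, and 8 and 12 for FoxO4. All 8 highest and all 8 lowest genes common to the 3 arrays had 1 probe set. Fbxo32 and Igf1 fall under the list part of the rule.

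Noise for simulated arrays came from the FoxO1 ratios of probe sets called unchanged, over 20 data sets. In the authors' deposited table these are 42320 of 45101 probe sets, so the simulated count for that array largely restates the spread of the same ratios. Whether the noise is too large or too small was not tested. The same noise served every array, so a count above the simulated one may come from noise set too low for the other arrays. Only the simulated FoxO1 ratio had no floor, so its excess cannot be set beside those of the other comparisons. The calculations were tested on simulated data for the array labelled FoxO1 against the control, with 18193 genes: 52.0% of 100 genes with a true 2-fold change and 89.0% of 100 with a true 4-fold change passed the threshold the right way, as did 33.5% of unchanged genes in either direction. Among the 4548 genes in the upper 25% by signal these shares were 55.0% of 20, 88.2% of 17 and 11.1% of 4511 genes. Array number limits the precision. Alternatives covered the probe sets used, the gene summary, the scaling, a filter on signal and the fold threshold. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.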

Results

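Expression was measured on 3 Affymetrix mouse arrays, 1 for each C2C12 myoblast line carrying a short hairpin RNA against FoxO1, FoxO3 or FoxO4. The lines were grown under puromycin from colonies picked for depletion of the intended FoxO gene, so hairpin and colony cannot be separated. Each array carried 45101 probe sets, of which 34958 have a single gene symbol, and these cover 18193 genes. The scaled signal had a median of 462.0 on the array labelled FoxO1, 387 on the array labelled FoxO3 and 398 on the array labelled FoxO4. There were no replicates, so no p-value or standard error is given, and every count of genes is a count by size only. A control RNAi array enters through the deposited log2 ratio of the array labelled FoxO1. The control signal implied by that ratio was also used for the other 2 arrays, a choice made after the values were seen.

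The first question was whether each targeted gene was low on its own array. Foxo1 went against its label: its log2 ratio to the control on the array labelled FoxO1 was 1.25 over 4 probe sets. The probe set with the highest Foxo1 signal read 2778 on the array labelled FoxO1, 563 on the array labelled FoxO3, 1827 on the array labelled FoxO4 and 1209 in the implied control. Of the 4 Foxo1 probe sets, 3 were higher on the array labelled FoxO1 than on both other arrays and in the implied control, and 1 of them carried an increase call. The remaining Foxo1 probe set was dim, at 106 on that array and 121 in the implied control. Foxo3 on the array labelled FoxO3 lay at -0.17 against the mean of the other 2 arrays. The 3 Foxo3 probe sets did not go 1 way. The brightest read 2380 on the array labelled FoxO1, 1573 on the array labelled FoxO3 and 386 on the array labelled FoxO4. The next Foxo3 probe set read 1357, 1047 and 1016 on these arrays, and the dimmest 174, 82.0 and 96.4. Against the implied control this dim Foxo3 probe set lay at -2.10, -3.19 and -2.95 on the arrays labelled FoxO1, FoxO3 and FoxO4, so it was low on all 3, and its signals on the last 2 were close to the floors of 73.1 and 77.3. Foxo4 on the array labelled FoxO4 lay at -0.58 against the other 2 arrays, from 2 probe sets that went opposite ways. One Foxo4 probe set read 80.4 on the array labelled FoxO4 against 1799 and 345 on the arrays labelled FoxO1 and FoxO3, a log2 difference of -3.29 that rests on a signal close to the floor of 77.3. The other Foxo4 probe set read 763 there against 188 and 163, a difference of 2.12. Foxo6 had no probe set. Because of Foxo1, every direction below is given for an array by its label and not for a known knockdown.

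**Figure D1:**
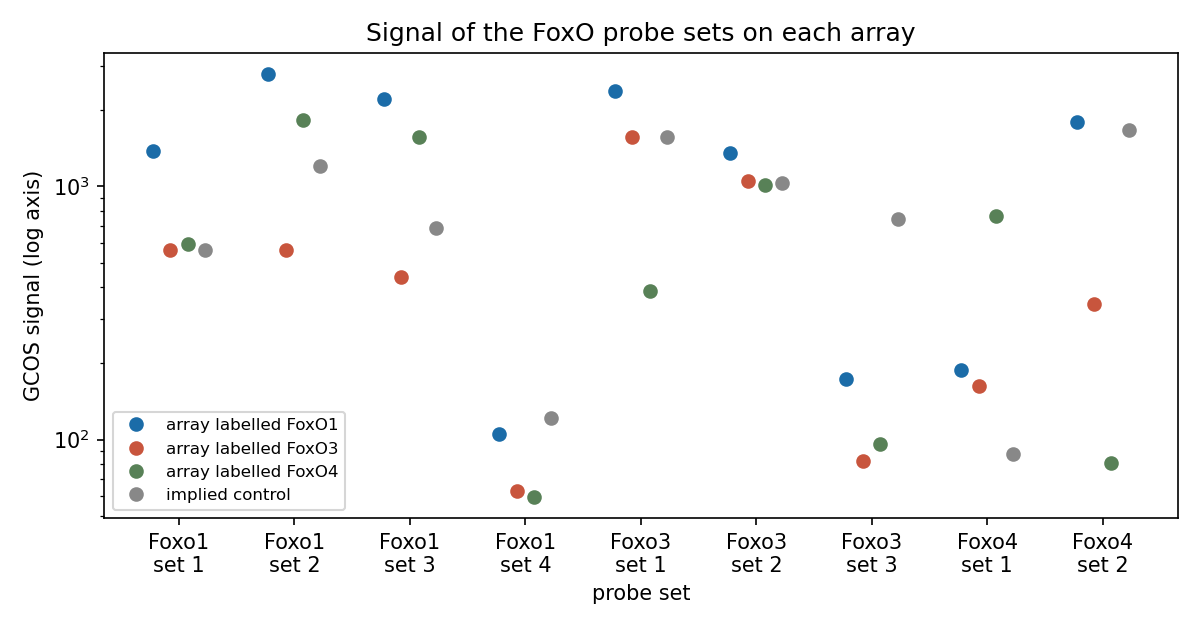
GCOS signal on a log axis for the 9 FoxO probe sets, with 1 point per array and 1 for the implied control. Among the 3 arrays, none of the 9 probe sets was lowest on the array labelled FoxO1, and the Foxo4 probe set at 80.4 on the array labelled FoxO4 stood at 1799 on the array labelled FoxO1.

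The array labelled FoxO1, where Foxo1 itself was high, was compared with the control through its deposited ratio. Genes of the sarcomere were low: the list median was -1.75 and 27 of 36 genes were at least 2-fold lower, among them Tnnc2 at -4.40, Neb at -4.30 and Actc1 at -4.10. Oxidative phosphorylation genes had a median of -0.80 with 35 of 90 at least 2-fold lower, including Cox8b at -4.50 and Cox6a2 at -2.75, and the median was -0.48 after quantile normalization. Cytosolic ribosomal protein genes had a median of -0.90, with 20 of 41 at least 2-fold lower. That median was -0.30 with plain probe sets only and -0.39 after quantile normalization, and Rps6 at -2.20 became -0.90 with its brightest probe set. The ribosomal and oxidative phosphorylation lists were drawn by the start of the gene symbol. They therefore also hold Rps19bp1 and the assembly factors Ndufaf1 to Ndufaf8, which are not subunits. Extracellular matrix genes were high, with a median of 1.10, 16 of 29 at least 2-fold higher, Postn at 4.70 and Col1a1 at 3.05. Fibroblast and smooth muscle markers were high on the same array, with a median of 0.70. Wnt pathway genes had a median of 0.90, with Sfrp2 at 4.40 and Ccn4 at 3.35 (2.10 with its brightest probe set). Cholesterol synthesis genes had a median of 0.60, with Cyp51 at 3.0 and Lss at 2.70 (1.10 with its brightest probe set), while heat shock genes lay at -0.82 with Hspb1 at -3.50 and Hspa1a at -2.30. Proliferation genes had a median of -0.50, with Aurkb and Mcm7 both at -1.40. Ccne1 and Myc of this list went the other way, at least 2-fold higher than the control here and on both other arrays. Of the 27 genes, 0 were at least 2-fold lower on all 3. The medians of 11 of the 33 lists fell outside the middle 95% of 10000 matched random lists, as a description of these libraries.

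Among single genes on this array, the highest ratios to the control were 6.80 for Smpdl3a, 5.80 for Col11a1, 5.50 for Slc1a6 and 5.25 for Mmp23. Among the lowest were -6.80 for Pdlim3, -5.80 for Dync1i1, -4.60 for Cth and Myoz2 and -4.55 for Nefl. Pdlim3, Cth, Myoz2 and Nefl carried decrease calls, and Col11a1, Slc1a6 and Mmp23 increase calls. Of the 12 highest genes named by the rule, 4 carried an increase call, and of the 12 lowest, 8 a decrease call. Most of them, 10 and 11, had 1 probe set. In all, 3419 genes were at least 2-fold higher and 3111 at least 2-fold lower, 6530 of 18193. The split was 3130 and 3138 after quantile normalization, and 383 and 559 among the upper 25% of genes by signal, an alternative chosen after the values were seen. Arrays simulated with no effect gave 6159 genes past 2-fold, with noise drawn from the same ratios over probe sets called unchanged. In a simulated data set 501 of 4511 unchanged genes in the upper 25% by signal passed 2-fold. In the authors' deposited table, for this array, 568 probe sets were called increased and 1900 decreased. By gene, 438 had increase calls alone and 1360 decrease calls alone.

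For the array labelled FoxO3, the comparison was with the mean of the other 2 arrays, 1 of which had the high Foxo1 signal. Matrix genes were low here, with a median of -0.97 and 14 of 29 at least 2-fold lower, led by Bgn at -8.81 (-6.74 with its brightest probe set) and Thbs1 at -3.90. Markers of osteoblasts and chondrocytes had a median of -1.51, with Alpl at -2.66, and Wnt pathway genes -0.94, with Wnt10b at -2.80. Proliferation genes were high, with a median of 0.80 and 12 of 27 at least 2-fold higher, including Ccne2 at 3.03 and Mcm4 at 2.26. Heat shock genes had a median of 0.59, with Hspb1 at 2.73. Against the implied control the matrix, osteoblast and chondrocyte, Wnt and heat shock medians of this array lay at -0.07, -0.50, -0.12 and -0.09, within the range of random lists, and proliferation at 0.60 above it. Against the other 2 arrays, the single genes furthest up were Nefl at 6.39 (5.15 with its brightest probe set), Mcpt8 at 5.90, Alox5 at 5.31 and Nefm at 5.28. Nefl was also among the lowest genes on the array labelled FoxO1 against the control, so its 6.39 is in part that array's low signal. Those furthest down after Bgn were Ogn at -7.71, Ptgis at -6.66 and Fam20a at -6.62. In total 2569 genes were at least 2-fold higher and 3045 lower, against 3682 in both directions with no simulated effect. Here and in the comparisons below the simulated noise came from the FoxO1 ratio, so an excess is not read as an effect. With each array centred on its median the split was 3134 higher and 2502 lower. The authors' deposited table called 1333 probe sets increased and 1224 decreased against the control.

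For the array labelled FoxO4, the comparison was also with the mean of the other 2, and 4 of 33 lists stood apart. By the same kind of comparison 7 did for the array labelled FoxO3 and 8 for the array labelled FoxO1. Against the control the counts were 11, 10 and 10 on the arrays labelled FoxO1, FoxO3 and FoxO4. Against the other 2 arrays, Wnt pathway genes had a median of 0.52, with Wnt10a at 2.09 and Lef1 at 2.04. Lef1 was under 2-fold at 0.87 with its brightest probe set. Matrix genes had a median of 0.37, with Bgn at 4.15 (3.10 with its brightest probe set) and Thbs1 at 2.5. Cholesterol synthesis genes lay at -0.37, and genes of the endoplasmic reticulum stress response at -0.32. Against the implied control these 2 lists lay at 0.22 and -0.09 on this array. Svep1 at 4.35, Ogn at 4.06 and Cd24a at 3.88 (1.96 with its brightest probe set) were among the highest, and Slc30a9 at -5.25, Lsm7 at -4.92, Mylpf at -4.75 and Stac3 at -4.38 among the lowest. At least 2-fold higher were 2440 genes and lower 2839, against 3651 in both directions with no simulated effect. The split was 2803 and 2505 after centring each array on its median. In the authors' deposited table, against the control, 1237 probe sets were called increased and 1472 decreased.

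The 3 arrays were also compared in pairs, each pair differing in hairpin and colony together. Bgn at 8.97 (6.93 with its brightest probe set), Ogn at 7.57 and Ptgis at 6.91 were highest on the array labelled FoxO1 over the array labelled FoxO3, and Nefl at -7.06 and Atf3 at -5.05 lowest. The matrix list stood 1.54 higher and proliferation -1.24 in that pair, with fibroblast and smooth muscle markers at 1.01. Over the array labelled FoxO4, the array labelled FoxO1 stood high for Mmp2 at 6.0 and Gpx3 at 5.54 and low for Leo1 at -4.57. Between the arrays labelled FoxO3 and FoxO4, Mcpt8 at 6.78 and Ackr3 at 6.48 were higher on the first and Bgn at -8.64 lower (-6.56 with its brightest probe set). At least 2-fold apart were 6438 genes for FoxO1 minus FoxO3 (3558 higher, 2880 lower), 6146 for FoxO1 minus FoxO4 (3408 and 2738) and 6088 for FoxO3 minus FoxO4 (2992 and 3096). Simulation with no effect gave 4542, 4538 and 4550. Centring each array on its median turned the first split to 2721 higher and 3789 lower, the second to 2710 and 3521 and the third to 3110 and 2964.

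Some genes stood at least 2-fold from both other arrays in the same direction. Those of the array labelled FoxO1 numbered 2891, 1678 higher and 1213 lower, with Mmp2 at 5.55 and Gpx3 at 4.68 highest and Leo1 at -4.14 lowest by the smaller difference. For the array labelled FoxO3 there were 2789, 1266 higher and 1523 lower, with Nefl at 5.72 and Bgn at -8.64 at the ends, or 3.82 and -6.56 with their brightest probe sets. For the array labelled FoxO4 there were 2544, 1144 higher and 1400 lower, with Svep1 at 3.81 and Slc30a9 at -4.92. Simulated arrays without effect gave 1882, 1901 and 1887 such genes. After centring, the first of these splits became 1202 higher and 1689 lower, the second 1547 and 1254 and the third 1325 and 1234.

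**Figure D2:**
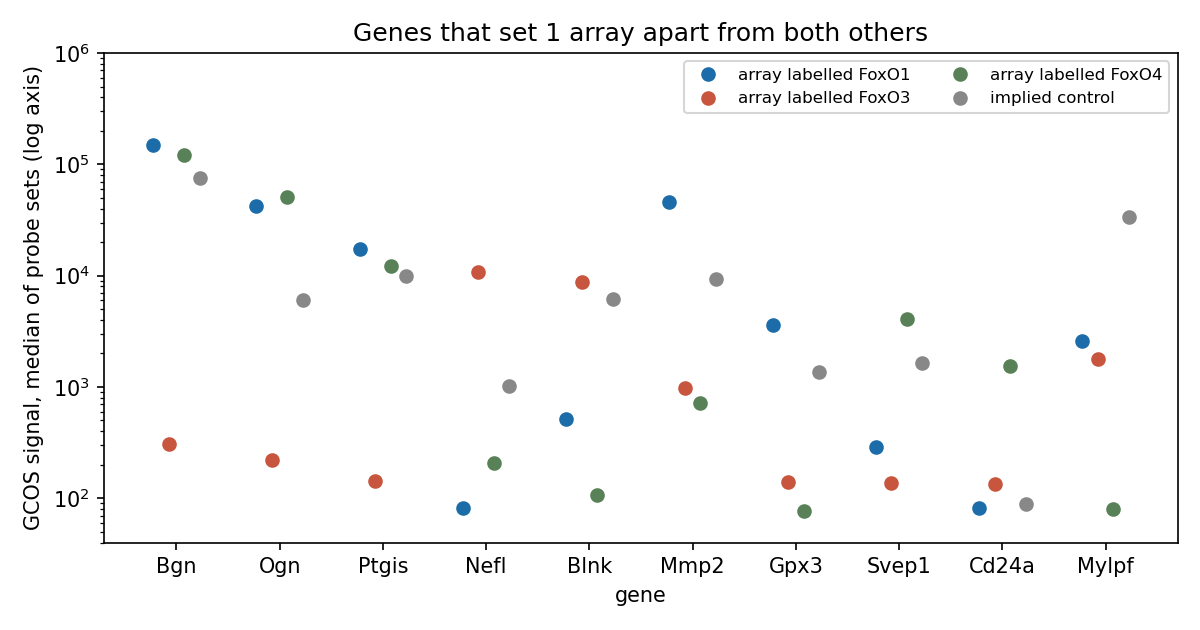
GCOS signal on a log axis, as the median of a gene's probe sets, for 10 genes on the 3 arrays and in the implied control. Ptgis read 143 on the array labelled FoxO3 and 17188 on the array labelled FoxO1, and Svep1 read 4042 on the array labelled FoxO4.

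Against the shared control, low muscle gene signal was common to the 3 arrays. The sarcomere list had medians of -1.75, -2.05 and -2.33 on the arrays labelled FoxO1, FoxO3 and FoxO4, and 21 of its 36 genes were at least 2-fold lower on all 3. Tnnc2 stood at -4.40, -7.62 and -7.98 and Actc1 at -4.10, -5.49 and -6.62. Of the 18 myogenic regulators, only 2 were at least 2-fold lower on all 3 arrays. These were Myog at -3.40, -5.43 and -7.47 and Mef2c at -2.80, -2.07 and -2.11. The brightest Mef2c probe set went the other way, at 2.40, 1.98 and 1.07. Cdkn1a was -2.25, -2.24 and -2.21, and Mt1 -3.95, -3.60 and -1.05. In the autophagy list Map1lc3a stood at -1.60, -2.94 and -1.96, and 2 of 22 genes were at least 2-fold lower on all 3. The list medians were -0.45, -0.61 and -0.09. The first lay at the lower bound of random lists, -0.45, and only the second lay outside their range. On that array, labelled FoxO3, 6 genes of the list were at least 2-fold lower and 4 higher. Oxidative phosphorylation medians were -0.80, -0.67 and -0.48 (the first 2 became -0.48 and -0.44 after quantile normalization), with 12 of 90 genes at least 2-fold lower on all 3 arrays. Matrix genes did not go 1 way on the array labelled FoxO3, where the list median was -0.07 with 7 of 29 at least 2-fold higher and 10 lower. Dcn was lower on all 3 arrays, at -3.80, -1.47 and -1.44, although its brightest probe set gave 0.99 on the array labelled FoxO4. Col4a1 was higher on all 3, at 1.35, 1.58 and 1.23, and Postn at 4.70, 2.35 and 4.89. The ubiquitin ligases of muscle atrophy did not stand apart, with medians of 0.00, -0.18 and 0.23, and Fbxo32 was -1.70 on the array labelled FoxO1. The 3' to 5' ratio of Actb was above the implied control's 2.56 on every array, at 6.31, 5.50 and 3.45. That of Gapdh was 5.0, 5.90 and 2.23 beside 2.68.

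**Figure D3:**
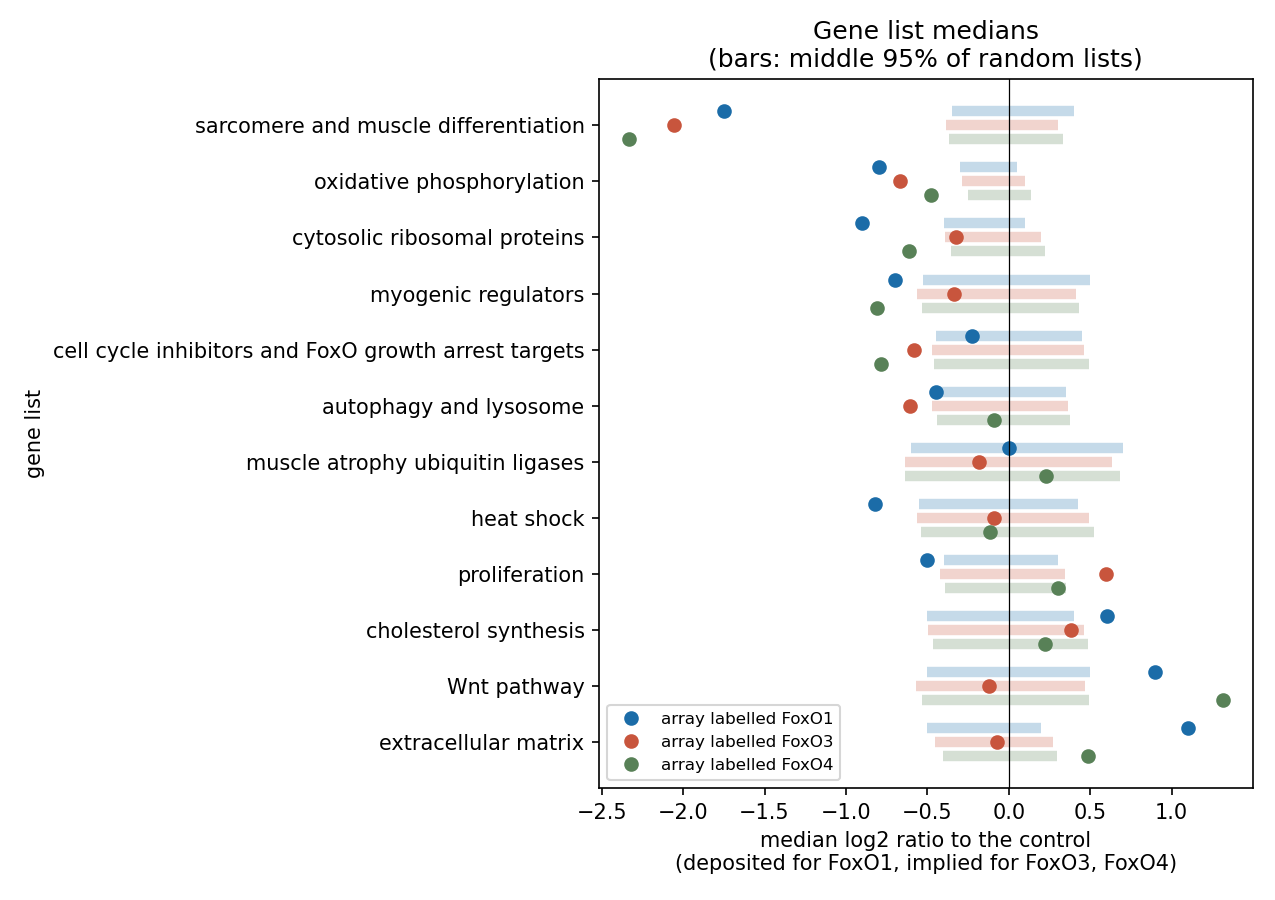
Median log2 ratio to the control of 12 gene lists on each array, with bars for the middle 95% of random lists. The sarcomere medians lie at -1.75, -2.05 and -2.33 and the matrix median of the array labelled FoxO1 at 1.10.

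Over all genes, 576 were at least 2-fold higher and 629 at least 2-fold lower on all 3 arrays against the control. With the brightest probe set per gene the counts were 944 and 626. Independent lists of these sizes would share 82 and 89, and simulated arrays with a shared control and no effect shared 421 and 711. The genes highest by the value nearest 0 were Tm7sf2 at 3.73 and Cenpi at 3.69, and the lowest were Tnnc2 at -4.40, Neb at -4.30, Actc1 at -4.10, Tnni1 at -4.10 and Cacna1s at -3.92. On the array labelled FoxO1, 1 of the 8 highest genes named by the rule carried an increase call, and all 8 lowest a decrease call. Across genes, which are not independent replicates, Pearson's r of the ratios was 0.35 for FoxO1 and FoxO3, 0.39 for FoxO1 and FoxO4 and 0.44 for FoxO3 and FoxO4, with Spearman's rho of 0.30, 0.36 and 0.41. The shared control alone gave 0.45, 0.45 and 0.49 in simulation. There the control was an array of its own, while the implied control was derived from the FoxO1 signal and ratio. The simulated overlaps, correlations and covariances therefore need not have the size that sharing gives in these data. Covariances were 0.51, 0.59 and 0.60 against 0.56, 0.56 and 0.48 simulated. The control could not be split, so none of this overlap is assigned to a shared effect.

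Further lists were compared with the control, which does not compare the arrays with each other. Growth arrest genes had medians of -0.22, -0.58 and -0.79 against the control, with Klf4 at -3.74 on the array labelled FoxO4 and Cdkn1c at -2.85 on the array labelled FoxO3. Notch genes lay at -0.35, -0.58 and -0.79, the last becoming -0.13 with the brightest probe set. Interferon response genes lay at -0.10, -0.67 and -0.73 and antioxidant genes at -0.20, -0.52 and -0.49. Cell adhesion genes had a median of -0.82 on the array labelled FoxO3. Insulin and IGF signalling genes did not stand apart, with medians of -0.05, -0.29 and -0.15. Igf1 was at 2.95 on the array labelled FoxO1 and 2.12 on the array labelled FoxO4. Of the 24 genes, 2 were at least 2-fold lower on all 3 arrays, Igf2 and Igfbp5, and 0 at least 2-fold higher. FoxO-linked lipid and energy genes lay at 0.10, -0.28 and 0.40, the first becoming 0.80 with the brightest probe set.

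Probe sets of the same gene give the only repeat measurement. For the FoxO1 ratio their correlation was 0.07 over 4695 genes with 2 probe sets, 0.62 over the 480 with both in the upper 25% of signal and 0.86 over the 150 with both in the upper 10%. The standard deviation of the difference between 2 probe sets of a gene was 2.08 over all 4695 genes and 0.50 in the upper 10%, beside a log2 threshold of 1.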

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

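Of the tests here, the test of 4 parts of a chromosome and the fit on gene length and signal level were written before their values were computed, and all others were chosen after the result was seen. The test of 4 parts was rewritten with a margin after its value was seen and then put back as first written.

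Array quality values stood out because they exceeded the implied control's by 1.5 times, a limit chosen after the values were seen. The 3' to 5' ratio of Gapdh was 5.0 and that of Actb 6.31 on the array labelled FoxO1, and 5.90 and 5.50 on the array labelled FoxO3, beside 2.68 and 2.56 in the implied control. The 18S signal was 12152, 12697 and 6971 on the arrays labelled FoxO1, FoxO3 and FoxO4 beside 3038. The median of proliferation genes against the control was -0.50 on the array labelled FoxO1 and 0.60 on the array labelled FoxO3, opposite directions. Compared directly, FoxO1 minus FoxO3 gave -1.24, below the range of -0.41 to 0.39 of matched random lists, but with 1 array each the difference between lines was not tested. Fibroblast and smooth muscle markers also went opposite ways, at 0.70 and -0.80, with a direct value of 1.01 above the range of -0.71 to 0.84, and this difference between lines was not tested either.

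Foxo1 signal was higher on the array labelled FoxO1 than on the others and than in the implied control. A cause in 1 aberrant probe set is argued against, since 3 of the 4 Foxo1 probe sets were higher there than on both other arrays and in the implied control. Whether the labels of the 3 arrays are exchanged among themselves stays open: no FoxO probe set was lowest on the array labelled FoxO1, so that 0 of the 6 label orders could give each targeted gene a probe set lowest on its own array, and this count decides nothing. Whether the array labelled FoxO1 and its control are exchanged could not be decided: 0 of the 4 Foxo1 probe sets were lowest in the implied control among the 4 arrays, but Foxo1 may also differ between colonies. For 1 of these probe sets the implied control, at 559.6, was level with the array labelled FoxO3, at 558.6, because the ratio behind it is rounded to 0.1. An effect of the hairpin on the measured transcript was not tested.

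Sarcomere genes were lower on all 3 arrays than in the implied control. Scaling is argued against as the whole cause, since after quantile normalization the list median nearest 0 was still -1.74. Loss of 5' signal stays open, with a median of -2.33 on the array labelled FoxO4. That array's Gapdh ratio of 2.23 was below the implied control's 2.68, while its Actb ratio of 3.45 was above 2.56. A control culture further along in differentiation may give the same picture, with the median nearest 0 at -1.75, and 1 control cannot separate this from an effect of depletion, which stays untested.

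Genes of the chromosome that carries Mdm2 and Igf1 (GRCm38.p6) sat lower on the array labelled FoxO4 than in the implied control, with a median of -0.36 over 440 genes, where the largest median of any chromosome stayed within 0.17 in 95% of 1000 permutations of genes. This chromosome was picked after its median was seen, among 120 chromosome values of which 17 lay outside their permuted range, and its genes did not all go 1 way, with Foxo3 at -2.03, Mdm2 at 0.59 and Igf1 at 2.12. Fewer copies in a line grown from a colony may be a cause but stay open, as the part nearest 0 of the 4 parts was -0.21, past the bound of -0.2 by less than 0.01. A loss on the array labelled FoxO4 alone could not be decided. The array labelled FoxO3 stood 0.43 above it, but the array labelled FoxO1 only 0.11. Gene length and signal level are argued against, since the median after a fit on both was -0.37.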

How the results depend on the processing

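The alternatives were planned before the data were examined except 5: the implied control for the arrays labelled FoxO3 and FoxO4, the floored FoxO1 signals for counts and for lists, FoxO1 against the mean of the other 2, and the genes of highest signal (the upper 25%). The other deposited table was not run as an alternative, because the signal table has no control column and the ratios of the arrays labelled FoxO3 and FoxO4 are not tied to identifiers. No paired analysis was possible because each line has 1 array.

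Counts by size stayed within 1.5 times the reported count in 54 of 100 cases, under the scaling, probe set and summary alternatives, with genes above the median signal and under the other reference arrays. Of the other 46, 40 were at another fold, by probe set or with 2 or more probe sets. Those at another fold or by probe set follow from construction, since they move the threshold or the features counted. The 10 with 2 or more probe sets were counted among 9010 genes. They also need all probe sets of a gene to agree, so their drop is not a matter of construction alone. The 6 lower counts among genes of high signal come in part from the number of genes, 4548 of 18193. For FoxO1 against control the share of unchanged genes past 2-fold was also smaller there in simulation, 11.1% against 33.5%, which was not simulated for the other 5. In the order FoxO1 against control, FoxO3 and FoxO4 against the others, FoxO1 minus FoxO3, FoxO1 minus FoxO4, FoxO3 minus FoxO4, only FoxO1, only FoxO3, only FoxO4 and all 3, the counts at 1.5-fold were 10128, 9447, 9064, 9854, 9507, 9493, 5091, 4942, 4552 and 2543. At 3-fold they were 3457, 2469, 2293, 3473, 3345, 3325, 1363, 1315, 1233 and 468. For probe sets in place of genes they were 19990, 17716, 17292, 19369, 18892, 18648, 9655, 8968, 8679 and 4269. For genes with 2 or more probe sets, all past the threshold, they were 587, 525, 400, 618, 477, 549, 144, 169, 88 and 30. In the upper 25% by signal the first 6 were 942, 877, 642, 1079, 810 and 1020, and the first of them split as 383 higher and 559 lower. Against the implied control, the arrays labelled FoxO3 and FoxO4 gave 5854 and 5937 genes.

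The median of all genes was -0.15 for the array labelled FoxO3 and -0.11 for the array labelled FoxO4 against the implied control as reported, and -0.22 for both after centring, while FoxO1 minus FoxO3 went from 0.15 to -0.10. The correlation of FoxO1 and FoxO4 ratios went from 0.39 to 0.50 among genes above the median signal. Foxo4 on the array labelled FoxO4 went from -0.58 to -3.29 with the brightest probe set, past 2-fold, because its 2 probe sets went opposite ways. Foxo1 on the array labelled FoxO1 stayed between 1.20 and 1.25.

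Of 371 alternatives for the 72 list medians outside the random range, 369 kept their direction. The median of apoptosis regulators for FoxO1 against control went from -0.50 to 0.10 with the brightest probe set, and that of cytosolic ribosomal proteins for FoxO4 against control from -0.61 to 0.30 with plain probe sets only. The cause was not tested for these or for the 42 list medians that follow. Some of the 42 lay inside the random range as reported and changed sign. Atrophy ligases (FoxO1 minus FoxO4) went from -0.41 to 0.62 with plain probe sets only. Ribosomal proteins (FoxO3 against control) went from -0.33 to 0.58 with plain probe sets only. Notch (FoxO1 minus FoxO3) went from 0.45 to -0.14 with the brightest probe set.

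With the brightest probe set the medians were 0.80 for FoxO-linked metabolism (FoxO1 against control), -0.14 for Notch (FoxO1 minus FoxO3) and -0.13 for Notch (FoxO4 against control). TGF-beta and BMP genes gave -0.71 (FoxO3 minus FoxO4), -0.83 (FoxO3 against control) and -0.90 (FoxO3 against others). Antioxidant genes gave -0.53 (FoxO1 minus FoxO4), heat shock -1.41 (FoxO1 minus FoxO3) and hypoxia 0.23 (FoxO1 minus FoxO4). Inflammation gave 0.59 (FoxO1 minus FoxO3) and 0.56 (FoxO1 against others), and leukocyte markers -0.74 (FoxO3 minus FoxO4) and 0.47 (FoxO4 against control). Neural markers gave 1.09 (FoxO3 against control) and 1.26 (FoxO3 against others), and the sarcomere list -2.73 (FoxO4 against control).

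With plain probe sets only, the medians were -0.58 for endoplasmic reticulum stress (FoxO4 against control), 0.48 for Wnt (FoxO3 against control), -0.35 for cholesterol synthesis (FoxO3 minus FoxO4) and -0.73 for heat shock (FoxO1 minus FoxO4). Ribosomal proteins gave -0.014 (FoxO1 minus FoxO4), -0.30 (FoxO1 against control) and 0.58 (FoxO3 against control). Leukocyte markers gave -1.07 (FoxO3 against control), atrophy ligases 0.62 (FoxO1 minus FoxO4), oxidative phosphorylation -0.35 (FoxO3 minus FoxO4) and the sarcomere list -1.94 (FoxO4 against control).

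Under quantile normalization ribosomal proteins gave -0.39, 0.049 and -0.17 for FoxO1, FoxO3 and FoxO4 against control, glycolysis 0.18 (FoxO1 against control) and oxidative phosphorylation -0.48 and -0.44 for FoxO1 and FoxO3 against control. After centring, ribosomal proteins gave -0.64 (FoxO1 against others) and oxidative phosphorylation -0.39 (FoxO1 minus FoxO3), -0.44 (FoxO1 minus FoxO4) and -0.39 (FoxO1 against others). Among genes above the median signal, adipocyte markers gave 0.52 (FoxO1 against others), epithelial markers -0.50 (FoxO3 minus FoxO4), leukocyte markers 0.61 (FoxO4 against control), osteoblast and chondrocyte markers -1.96 (FoxO3 minus FoxO4) and the sarcomere list -2.41 (FoxO3 against control).

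Over 230 values of named genes and their alternatives, 857 moved by less than a log2 of 1, 28 by more with the same direction, and 4 changed direction, all with the brightest probe set: Mef2c, at 2.40, 1.98 and 1.07 against control on the arrays labelled FoxO1, FoxO3 and FoxO4, and Dcn, at 0.99 against control on the array labelled FoxO4. The cause was not tested. The 28 belong to Bgn, Nefl, Nrep, Cd24a, Fmod, Rps6, Ccn4, Lss, Lef1 and Dcn, whose value on the array labelled FoxO1 became -6.40. With the brightest probe set, Rps6 at -0.90, Lef1 at 0.87 and the smaller difference of Cd24a on the array labelled FoxO4 from the other 2, at 0.86, were under 2-fold. Agreement of a gene's probe sets on the FoxO1 ratio was 0.07 over all 4695 genes compared and 0.86 over the 150 with both in the upper 10% of signal.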

Other observations

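In the authors' deposited table, 5.47%, 5.67% and 6.01% of probe sets carried an increase or decrease call for the arrays labelled FoxO1, FoxO3 and FoxO4. The log2 signals of the 3 arrays correlated with each other at r of 0.70, 0.70 and 0.72 across probe sets. With the implied control r was 0.78 for the array labelled FoxO1, from whose signal the control is derived, and 0.74 for both other arrays.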
